A study of Mus musculus with 6 samples.

How the data were processed

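RNA sequencing of bone marrow-derived macrophages from C57BL/6J mice was analysed in 6 libraries. Per the labels, 3 libraries came from control cells and 3 from cells of a macrophage-specific Dhps knockout. Bone marrow-derived macrophages are cells grown out of marrow progenitors in culture. Libraries were sequenced on an Ion Proton instrument, per the labels' protocols. The labels name no stimulus, no growth factor and no Cre driver, and they do not say whether the libraries of a group came from separate animals or cultures. The p-values below therefore measure only the spread between these samples, which may be technical.

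The deposited table gives raw read counts per gene, as whole numbers that the authors had not normalized, together with exon coordinates and a summed exon length of each gene in bases. The deposited length is another kind of value than a count and was used only to test for a length trend. The submitters' processing notes name STAR 2.4.2a, featureCounts, Subread 1.5.0, edgeR and the mouse build mm10. They give neither the role nor the order of these tools. The gene annotation and the use of strand in counting were not given in the sources used here. The table held 10551 genes, and in each of them the third highest value exceeded 1 CPM (counts per 1000000 counts of the library), so that at least 3 libraries lay above that floor. The deposited table therefore looks filtered at that level by the authors. The order of its rows followed the p-values computed here, with a Spearman rho of 0.871 across genes, which are not independent replicates. 17 gene symbols had the form of calendar dates, and a symbol that occurred on more than 1 chromosome was kept apart by chromosome. 0 columns of per-sample values were left unused.

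The total count per library over these genes lay between 11648710 and 16224818. Library sizes were scaled with the trimmed mean of M values (TMM), and values per library are given as normalized CPM. The expression filter filterByExpr with a minimum count of 10 removed 0 genes. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as the only term. P-values were adjusted with the Benjamini-Hochberg method over all 10551 genes, and a gene was called changed at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of its F statistic. The biological coefficient of variation was 10.7%. Fold changes are given as Dhps knockout relative to control.

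37 gene lists, for macrophage functions and for markers of other cell types the cultures could hold, were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 34 lists with at least 3 measured members were adjusted together. Camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move on balance 1 way, were run beside it. Estimating the correlation also refers camera's statistic to the 4 residual degrees of freedom, far fewer than with the preset value. A call lost there can therefore come from either change. Intervals of list medians came from 2000 bootstrap draws over members and do not include the spread between libraries. Counts of members past the threshold are given over all genes and adjusted over the list alone.

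The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Dhps, up to 12 genes each way past the threshold with no overlap between the groups, up to 5 each way that came next by p where fewer passed, up to 4 members of each list with the smallest p, the 5 largest changes each way past the threshold with an average log2 CPM of at least 2, Lyz2, and the annotated neighbours of Dhps. Gene models without a name were counted and not named, and some genes that the rule takes are not reported here. Tnf, Il1b, Nos2, Eif5a, Dohh, Lyz1, Xist, Malat1, Vwf, Csf3r, Mmp8, Wfdc21, Gp9, Ccl7, Camp, Mpo and Prtn3, as well as list members beyond the first 4, were chosen after their values were seen.

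Alternatives were other size factors, no size factors, no filter, a stricter filter, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a minimum fold of 1.5, an adjusted p under 0.1 and other list tests. Leaving Lyz2 out of the counts was added after seeing the data. Gene coordinates are those of the deposited table (mm10). GC content and overlaps of exons were taken from the GENCODE annotation of the same assembly.

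The gene test was tested on simulated data for the comparison of knockout with control, with counts drawn for the 10551 genes from the means of the real libraries. It recovered 34 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 63 of 66 changed 3-fold, with 5 false calls among 159. Many more genes were called there than the 11 of the real data, which eases the adjusted threshold. The simulated counts also held no effects of single libraries shared by genes. These shares may therefore overstate the recovery in the real data. In the test of the list step, 1 list shifted by 0.4 on the log2 scale was called, and 0 of the other 33 lists were. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called falsely. The shift was also larger than the medians of all lists called lower in the real data. No pair of libraries within a group agreed within sampling noise (the lowest chi-square per degree of freedom was 7.27), and each library was counted as a replicate. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, and none was used.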

Results

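Gene expression was compared between control macrophages and macrophages with a macrophage-specific knockout of Dhps. Dhps encodes deoxyhypusine synthase, the enzyme that starts the hypusine modification of the translation factor eIF5A. The series' title frames the question as the role of this enzyme in the pro-inflammatory state of macrophages. The 3 control libraries held 14334262, 15382816 and 11648710 counts, and the 3 Dhps knockout libraries held 14197323, 12960793 and 16224818. Libraries were alike across genes, with a Pearson r of log2 CPM between 0.987 and 0.991 within groups and between 0.986 and 0.990 across groups.

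Dhps transcript lay at 22.8 ± 1.67 CPM in control and 15.0 ± 2.86 CPM in knockout libraries (SD, n = 3 each), a log2 fold change of -0.59 (SE 0.14, 95% interval -0.89 to -0.30). Each knockout library lay below each control library, with 13.2, 13.6 and 18.3 CPM against 24.1, 20.9 and 23.4 CPM. The difference did not pass the threshold over all genes in edgeR's quasi-likelihood test (adjusted p = 0.214), though it did with the replicate number as a block (adjusted p = 0.033). Dhps spans bases 85071757 to 85075161 of chromosome 8 in mm10, on the plus strand, with 9 exons. Which part of the gene was deleted was not given in the sources used here, and counts over all exons include reads from outside that part. The last 127 bases, from 85075035 to 85075161, are also exonic in Wdr83 on the opposite strand, so that reads from this stretch could belong to either gene. The neighbouring genes Wdr83 (log2 fold change -0.31, adjusted p = 0.920) and Fbxw9 (-0.11, adjusted p = 0.968) did not pass the threshold.

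Of 10551 genes, 10 rose and 1 fell in the knockout libraries. The gene that fell was Lyz2, which encodes the lysozyme of macrophages and other myeloid cells and was among the most abundant transcripts. Its close paralog Lyz1, with which it could share reads, lay at 28.3 CPM in control and 25.3 CPM in knockout libraries (log2 fold change -0.16, adjusted p = 0.876). Lyz2 went from 18039 ± 1542 CPM to 8765 ± 701 CPM (SD, n = 3 each), a fold of 0.486 and a log2 fold change of -1.04 (SE 0.097, adjusted p = 7.2e-05). The largest group among the genes that rose encodes granule and antimicrobial proteins of neutrophils and their precursors. Ngp, neutrophilic granule protein, rose from 31.5 ± 4.56 to 74.1 ± 11.6 CPM (log2 fold change 1.24, SE 0.13, adjusted p = 1.5e-04). S100a8 (0.95, adjusted p = 4.3e-04) and S100a9 (0.85, adjusted p = 0.0061), the subunits of calprotectin, rose, as did Lcn2 (0.87, adjusted p = 0.0026), which binds bacterial siderophores, and Ltf (0.96, adjusted p = 0.0080), which encodes lactoferrin. Eif1, a factor in the choice of the start codon, rose 1.47-fold from 136 ± 2.16 CPM in control libraries (log2 fold change 0.56, SE 0.085, adjusted p = 0.0081). The chemokine gene Ccl8 rose by 0.59 on the log2 scale (SE 0.094, adjusted p = 0.012). The remaining genes that rose encode secreted proteins of the extracellular matrix: Col1a2, a chain of fibrillar collagen (2.82, SE 0.51, adjusted p = 0.046), Sparc (2.34, SE 0.43, adjusted p = 0.046) and Fstl1 (1.01, SE 0.19, adjusted p = 0.046). Col1a2 and Sparc were close to the floor of the table, at 0.393 and 0.582 CPM in control and 2.76 and 2.89 CPM in knockout libraries. Both exceeded 1 CPM in all 3 knockout libraries and in no control library, and so are in the table through the knockout libraries alone, as are 31 genes in all, against 3 through the control libraries alone.

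**Figure D1:**
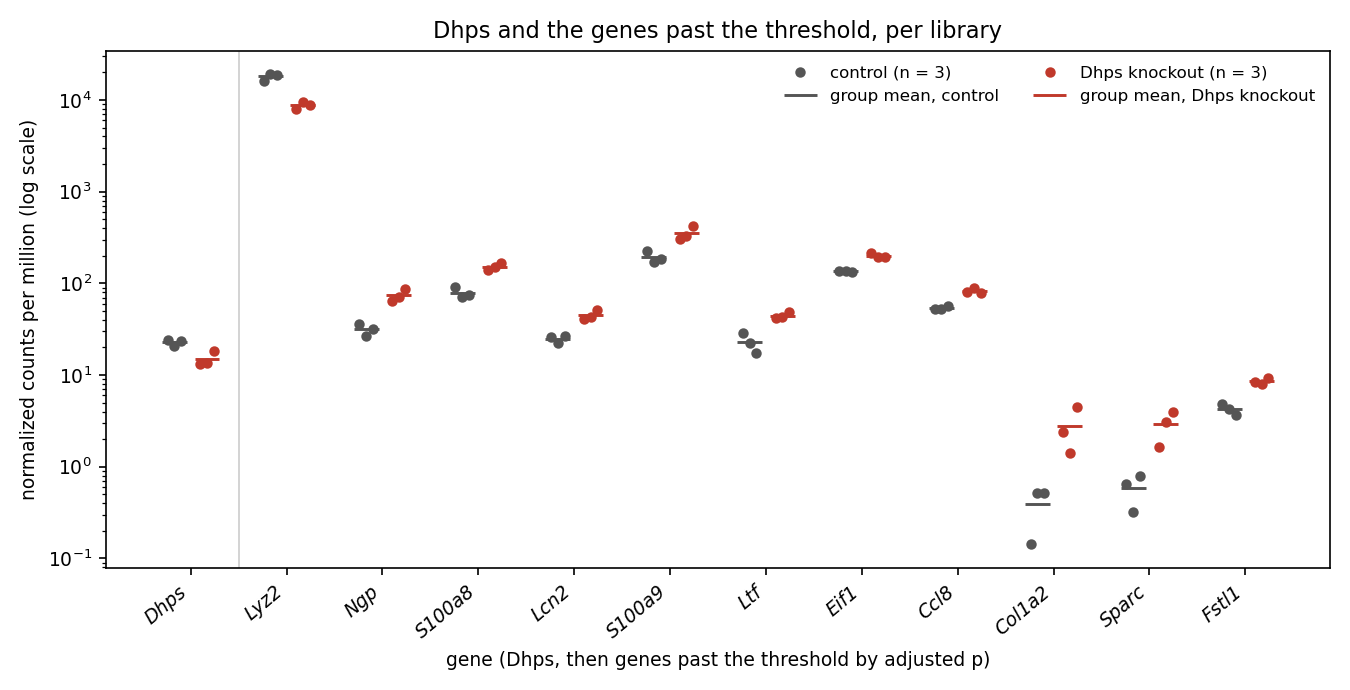
Normalized CPM on a log axis for Dhps and the 11 genes past the threshold, with 1 point per library, control in grey and Dhps knockout in red (n = 3 each), and a bar at each group's mean. Lyz2 goes from a mean of 18039 to 8765 CPM.

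In mm10 coordinates, Lyz2 lies on chromosome 10 (117277541 to 117282272), Ngp and Ltf on chromosome 9 (110419808 to 110423012 and 111019292 to 111042766), and S100a8 and S100a9 on chromosome 3 (90669071 to 90670034 and 90692630 to 90695721). Lcn2 lies on chromosome 2 (32384637 to 32387739), and Eif1 and Ccl8 lie on chromosome 11 (100319996 to 100322096 and 82115185 to 82116799). None of the 11 genes overlaps an exon of another annotated gene. At an unadjusted p under 0.05, 405 genes were higher and 279 lower, 684 in all, where 528 would be expected from uniform p-values. Other splits of the 6 libraries into 3 and 3 gave up to 1068, so this excess cannot be assigned to genotype. Next by p among the genes that did not pass, gene models without a name left out, came Timp3 (1.34, adjusted p = 0.052, and 0.021 without control library 1), Arhgap26 (0.88, adjusted p = 0.110) and Mcpt8 (2.00, adjusted p = 0.110), then Sla (0.75) and Abca13 (0.93), on the higher side. On the lower side they were Npy (-0.58, adjusted p = 0.114), Dhps, Cadm1 (-0.58, adjusted p = 0.018 without knockout library 2), Idh2 (-0.45) and Kcnn4 (-0.40).

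Leaving out 1 library, which also lowers the number of samples, ended the call for part of these genes, while their log2 fold changes kept their sign. Lyz2, Ngp, S100a8 and Lcn2 passed with each of the 6 libraries left out in turn. Without control library 2, S100a9 and Ltf did not pass (adjusted p = 0.082 and 0.084). Eif1 did not pass without control library 2 or control library 3 (adjusted p = 0.082 and 0.073), nor Ccl8 without control library 2 or knockout library 2 (adjusted p = 0.133 and 0.137). The log2 fold change with 1 library left out ranged from 0.70 to 0.98 for S100a9, 0.80 to 1.16 for Ltf, 0.52 to 0.59 for Eif1 and 0.54 to 0.63 for Ccl8. Col1a2 passed only without knockout library 1 or 2, Sparc only without knockout library 1 and Fstl1 only without control library 1, with adjusted p of up to 0.238, 0.405 and 0.344 and log2 fold changes from 2.27 to 3.12, 2.03 to 2.63 and 0.93 to 1.11. The number of genes called was 4 without control library 2, 7 without control library 3 and 19 without control library 1, and DESeq2 called 22 genes, which included all 11. Of the genes named above as not passing, DESeq2 called Timp3 (adjusted p = 0.0059), Npy (0.015), Arhgap26 (0.022), Sla (0.027) and Abca13 (0.039).

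Of the lists of markers of other cell types, 5 were called higher in the knockout libraries with the preset correlation, and none with an estimated correlation. Of 13 measured markers of neutrophils and their precursors, 5 rose (Ngp, S100a8, Lcn2, S100a9 and Ltf), and 8 did not pass. Adjusted over the list alone 9 rose, the others being Mpo (0.93), Prtn3 (1.14), Camp (0.66) and Wfdc21 (0.95), which ranged from 0.42 to 0.85 and from 0.63 to 1.18 with 1 library left out. The median log2 fold change of the list was 0.87, and camera called it higher (adjusted p = 3.0e-13, adjusted p = 0.210 with an estimated correlation). Of 9 megakaryocyte and platelet markers none passed over all genes. Adjusted over the list alone 4 rose, Ppbp (0.77), Itga2b (0.64), Tubb1 (1.54, from 1.22 to 2.35 with 1 library left out) and Gp9 (1.11), and 1 fell, the platelet chemokine Pf4 (-0.29), which lay at 1517 CPM in control libraries. Tubb1 and Gp9 are in the table through the knockout libraries alone. The list's median was 0.64 (bootstrap 95% interval -0.12 to 1.11, camera adjusted p = 2.1e-04, adjusted p = 0.210 with an estimated correlation). Of 13 mast cell and basophil markers 5 were measured. None passed over all genes, and Mcpt8 (2.00) and Prss34 (1.70) rose when adjusted over the list alone, from 0.471 and 0.698 CPM in control libraries. Both are in the table through the knockout libraries alone. The list median was 0.31 (bootstrap 95% interval -0.11 to 2.00, camera adjusted p = 5.0e-04, adjusted p = 0.418 with an estimated correlation). It was 0.57 without control library 2, 0.18 without knockout library 3 and above 1 with the stricter filter, which asks for 1 CPM in every library of a group. That filter keeps Mcpt8 and Prss34 through the knockout libraries alone, so the higher median does not show a larger effect.

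The 13 measured monocyte markers had a median log2 fold change of 0.32 (camera adjusted p = 0.0020, adjusted p = 0.210 with an estimated correlation). None passed over all genes, and adjusted over the list alone 3 rose: Plac8 (0.86, adjusted p = 0.031 over all genes without knockout library 1), the haptoglobin gene Hp (0.64) and Spn (0.79). Of 21 stromal and fibroblast markers 8 were measured and 2 rose, Col1a2 and Sparc, both over all genes and adjusted over the list alone, while Postn (0.41, adjusted p = 0.861) and Col5a2 (1.60, adjusted p = 0.748) did not pass. The stromal list had a median of 0.47 (bootstrap 95% interval -0.0092 to 2.34, camera adjusted p = 0.0034, adjusted p = 0.418 with an estimated correlation), and of 0.29 without knockout library 3. Since Col1a2 and Sparc are in the table through the knockout libraries alone, the floor favours a higher call for this list, and it was not tested without them. Without control library 3 the mast cell and basophil list was not called (adjusted p = 0.051), nor was the stromal list without control library 2 (adjusted p = 0.095). The 4 B and plasma cell markers (median 0.33, adjusted p = 0.076, and 0.046 without control library 1), the 4 endothelial and adipocyte markers (0.17, adjusted p = 0.140, and 0.036 without control library 1) and the 6 dendritic cell markers (-0.043, adjusted p = 0.960) did not pass, and with an estimated correlation and all libraries the B and plasma cell and endothelial lists had an adjusted p of 0.418 and 0.713. Erythroid markers and T and NK cell markers, with 1 and 2 measured members, were not tested.

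Inflammatory cytokines and mediators showed no difference that passed. Whether the cells had been stimulated was not given in the sources used here. The comparison covers cells that already expressed Il1b, Tnf and Nos2 at the levels below in both groups. It does not cover cells without that expression. Of 25 measured members none rose or fell, over all genes or adjusted over the list alone, and the median log2 fold change was -0.0010 (bootstrap 95% interval -0.10 to 0.13, camera adjusted p = 0.966). Il1b was at 4483 ± 362 CPM in control and 4180.0 ± 117 CPM in knockout libraries, Tnf at 2176 ± 270 and 1992 ± 58.8 CPM, and Nos2, the inducible nitric oxide synthase gene, at 3045 ± 348 and 3043 ± 358 CPM (SD, n = 3 each). The 95% interval of the log2 fold change was -0.29 to 0.09 for Il1b, -0.33 to 0.08 for Tnf and -0.22 to 0.22 for Nos2. The members with the smallest p were Il27 (-0.28, adjusted p = 0.414), Lif (0.54, adjusted p = 0.495) and Il18 (-0.32, adjusted p = 0.588). The 28 genes of the NF-kB pathway (median -0.018, adjusted p = 0.802) had no member that passed. The 38 interferon-stimulated genes (-0.043, adjusted p = 0.212) had none either, but as a set were called lower without control library 2 (adjusted p = 0.024) or knockout library 3 (adjusted p = 4.8e-05). With all libraries that list had an adjusted p = 0.918 with an estimated correlation.

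Of 19 chemokine genes 1 rose, Ccl8, and 18 did not pass. Adjusted over the list alone Ccl8 rose and 4 fell: Pf4 (-0.29), Cxcl1 (-0.35), Ccl24 (-0.56) and Ccl7 (-0.46). With 1 library left out, Ccl24 ranged from -0.77 to -0.37, Cxcl1 from -0.46 to -0.22 and Ccl7 from -0.63 to -0.29. The list as a whole was not called (median -0.037, camera adjusted p = 0.406). Of 30 genes of macrophage identity and phagocytosis none passed over all genes, and adjusted over the list alone 2 fell, C1qc (-0.33) and C1qa (-0.28), which encode chains of complement component C1q. The median of this list was -0.015 (camera adjusted p = 0.414). In the alternative activation list Cd163, a scavenger receptor for haemoglobin, rose when adjusted over the list alone (2.06, adjusted p = 0.142 over all genes and 0.0084 with DESeq2), from 0.825 CPM in control libraries, and the list of 23 was not called (adjusted p = 0.533). Of 9 genes of MHC class II presentation only Ciita (-0.38, adjusted p = 0.043 over all genes without control library 1) fell when adjusted over the list alone, and the list was not called (adjusted p = 0.869). Of these 9 genes, 6 had an unadjusted p under 0.05, against 684 of all 10551. Log2 fold changes were above 0 for 5 and below for 4, and camera looks for a shift 1 way. The form of fry for changes either way gave an unadjusted p = 0.089.

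The hypusine and polyamine pathway, which holds the substrate of the deleted enzyme, had 12 measured members and none that passed, over all genes or adjusted over the list alone (median 0.033, camera adjusted p = 0.944). Eif5a lay at 329 ± 20.1 CPM in control and 327 ± 19.9 CPM in knockout libraries (SD, n = 3 each), with a 95% interval of the log2 fold change of -0.19 to 0.18. Dohh, the next enzyme of hypusine formation, had a log2 fold change of -0.11 (adjusted p = 0.961) and Odc1, which makes putrescine, -0.17 (adjusted p = 0.837). Among 46 translation initiation and elongation factors 1 rose, Eif1, over all genes and adjusted over the list alone, and the list was not called (median -0.048, adjusted p = 0.533). The integrated stress response list, with Atf4 at -0.20 and Trib3 at 1.06, was not called (adjusted p = 0.944).

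The 75 cytosolic ribosomal protein genes had a median log2 fold change of -0.071, with 60 below 0 and none that passed, over all genes or adjusted over the list alone. Among its members, Rps14 had a log2 fold change of -0.20 (adjusted p = 0.737). The list was called lower (camera adjusted p = 0.0043, adjusted p = 0.907 with an estimated correlation). The call was lost without control library 1 (adjusted p = 0.057, median -0.047), control library 2 (0.190, median -0.035) or knockout library 2 (0.714, median -0.0058), while the median was -0.12 without control library 3 and also without knockout library 1. Of 13 listed mitochondrially encoded genes 0 were measured, so that list was not tested. The 62 nuclear genes of oxidative phosphorylation had a median of -0.069, with 47 below 0 and none that passed by either adjustment. Ndufs7 (-0.32) and Ndufa6 (-0.23) had the smallest p, and the list was called lower (camera adjusted p = 0.0020, adjusted p = 0.306 with an estimated correlation), though not without control library 1 (adjusted p = 0.052). Removing a trend with gene length ended the calls of the ribosomal and oxidative phosphorylation lists (adjusted p = 0.215 and 0.120). Of the 26 genes of the TCA cycle only Idh2 (-0.45) fell when adjusted over the list alone, and the list was not called (adjusted p = 0.102, and 0.030 without knockout library 2, adjusted p = 0.523 with an estimated correlation and all libraries).

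Further lists had small medians and no member that passed by either adjustment. The 15 genes of MHC class I presentation were called lower as a set (median -0.10, camera adjusted p = 0.016, adjusted p = 0.713 with an estimated correlation), with Nlrc5 at -0.23 and H2-K1 at -0.20. The 23 cholesterol biosynthesis genes were called lower (median -0.11, camera adjusted p = 0.028, adjusted p = 0.523 with an estimated correlation), with Fdps at -0.39 and Cyp51 at -0.23. The 22 immediate-early genes were called higher (median 0.13, camera adjusted p = 0.0051, adjusted p = 0.713 with an estimated correlation), with Nr4a3 at 0.43 and Egr1 at 0.55. The MHC class I call was lost without control library 1 (adjusted p = 0.211, median -0.061), control library 3 (0.055) or knockout library 1 (0.377, median -0.046), while its median was -0.16 without knockout library 3. After a trend with gene length was removed from each library it was also lost (adjusted p = 0.067), though the median on mean log2 CPM went only from -0.095 to -0.075 (bootstrap 95% interval -0.13 to -0.032). The cholesterol call was lost without control library 2 (0.190), control library 3 (0.064) or knockout library 1 (0.135), and the immediate-early call without control library 2 (0.088, median 0.083) or knockout library 3 (0.346, median 0.022).

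**Figure D2:**
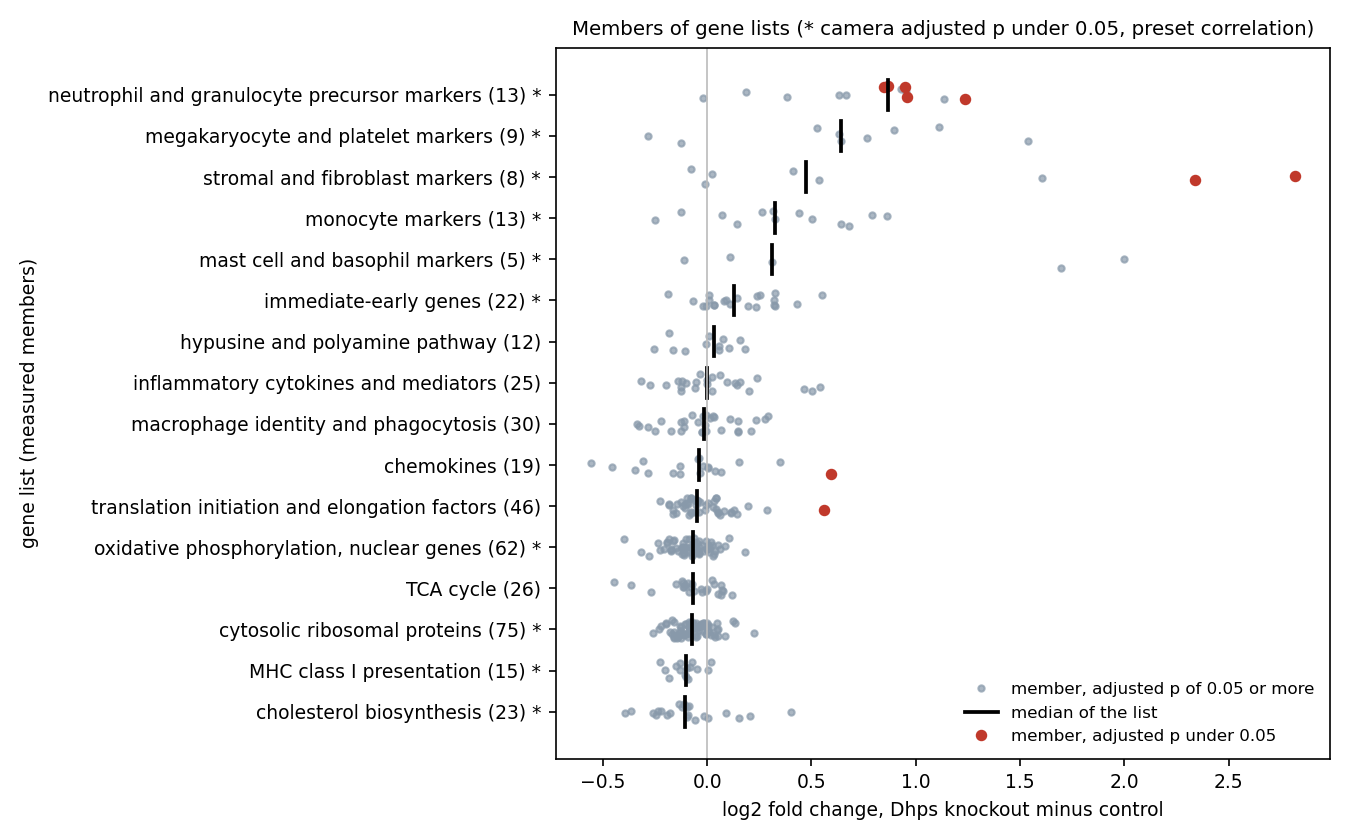
Log2 fold change (Dhps knockout minus control) of each measured member of 16 gene lists, 1 point per gene, with red points for members past the threshold and a black bar at each list's median. The neutrophil and granulocyte precursor list lies farthest to the right, with a median of 0.87 and 5 members past the threshold, while the inflammatory cytokine list is centred at -0.0010.

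In all, 10 of 34 lists were called by camera with the preset correlation, 6 higher and 4 lower. With an estimated correlation 0 lists were called, and fry called 0. For the megakaryocyte and monocyte lists the estimated correlation was 0.013 and -0.018, near the preset 0.01. Correlation between genes alone therefore does not account for the loss of these 2 calls. The lists of chemotaxis and adhesion receptors (median 0.082, adjusted p = 0.215), NRF2 targets (0.048, 0.366), glycolysis (-0.041, 0.484) and autophagy and lysosome genes (0.015, 0.581) did not pass. The same held for the actin cytoskeleton (-6.0e-05, 0.616), LXR and PPAR lipid handling (-0.027, 0.666), p53 targets (0.023, 0.869), endoplasmic reticulum chaperones (-0.0088, 0.989) and the cell cycle (-0.0062). Osteoclast genes (0.036, 0.772) did not pass as a list, though Itgb3 (0.60, adjusted p = 0.021 over all genes without control library 1) rose when adjusted over the list alone. Median, mean and test direction differed in sign for the lists of inflammatory cytokines, MHC class II, hypusine and polyamines, the integrated stress response, dendritic cells, endoplasmic reticulum chaperones, the cell cycle, p53 targets and the actin cytoskeleton, none of which was called.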

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

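Leaving Lyz2 out of the counts was the test chosen only after the result was seen; the other alternatives were planned. The number of genes called was 11, and 8 to 12 under other size factors, no size factors, no filter, a stricter filter, limma-voom, a minimum fold of 1.5 or an adjusted p under 0.1. It was 22 with DESeq2 and 7 with Lyz2 left out of the counts, where Lyz2 was not tested and Col1a2, Sparc and Fstl1 moved from an adjusted p of 0.046 to 0.051. With 1 library left out it ranged from 4 to 19. The filter removed no gene, so the setting without it tests nothing. The Dhps log2 fold change ranged from -0.76 to -0.50 with 1 library left out (adjusted p from 0.076 to 0.660), and DESeq2 gave an adjusted p of 0.080. Timp3 passed with other size factors (adjusted p = 0.0499), no size factors (0.035), the stricter filter (0.048), the replicate number as a block (0.014), without control library 1 (0.021) and with DESeq2 (0.0059). The number of lists called was 10, between 7 and 10 with 1 library left out, 0 with an estimated correlation and 0 with fry. The mast cell and basophil median moved from 0.31 to above 1 with the stricter filter, which keeps Mcpt8 and Prss34 through the knockout libraries alone. The ribosomal median moved from -0.071 to -0.046 with no size factors, where the median of all genes moved as well, from -0.0044 to 0.019.

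The labels number the libraries of both groups and do not say that equal numbers are paired. The correlations of same-numbered libraries' deviations from their group means were 0.139, 0.0195 and 0.148. Across the groups, libraries of different number had -0.181 to 0.0548, and libraries 1 and 3 correlated best with their own number. A pairing therefore stays open, and the block is given as an alternative. With the replicate number as a replicate block, 35 genes were called (26 higher, 9 lower), including all 11, and the Dhps log2 fold change was -0.61 (adjusted p = 0.033). Among genes named above as not passing, the block also called Timp3, Npy, Arhgap26, Sla, Abca13, Cadm1, Cd163, Ppbp, Itgb3, Ccl24 and Ccl7. With the preset correlation 10 lists were called. With an estimated correlation none was (lowest adjusted p = 0.712). The block leaves fewer than 4 residual degrees of freedom, so that test could hardly call any list. Control library 2 correlated best with knockout library 1, not with its own number.

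Among single genes, 2266 values kept their side of the threshold, 26 fell back below it and 29 came to pass. Among lists these were 437, 34 and 5. Of the values that kept their side, 30 of genes and 38 of lists that were not called changed sign. No called value changed sign in any of these settings, and the cause of the other shifts was not tested. Depth limits the genes near 1 CPM: of the 11 genes called, 2 had a control mean under 2 CPM.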

Other observations

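The tests of granulocyte-lineage RNA and of each explanation for Lyz2, and the split of camera's statistic into shift and SE, were chosen only after the result was seen, and those of length, GC content, sample splits, flanking DNA and single knockout libraries were written before their results. Malat1, a nuclear long non-coding RNA, lay at 666 ± 76.8 CPM in control and 960 ± 175 CPM in knockout libraries (SD, n = 3 each), with a log2 fold change of 0.53 (adjusted p = 0.186, 0.013 without knockout library 1, 0.033 with the replicate block and 0.017 with DESeq2). Xist, also a nuclear non-coding RNA, was detected in all 6 libraries, at 29.1, 37.5 and 45.1 CPM in control and 47.5, 69.1 and 52.2 CPM in knockout libraries (log2 fold change 0.60, adjusted p = 0.290, and 0.014 with the replicate block). Among the genes that did not pass, gene models without a name left out, Npy (52.1 to 34.8 CPM), Cadm1 (46.4 to 31.1 CPM), Idh2 (59.8 to 43.9 CPM) and Kcnn4 (203 to 153 CPM) had the smallest p on the lower side besides Dhps.

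Lyz2 fell to 48.6% of its control level in the knockout libraries. A smaller share of macrophages would lower other macrophage genes too, but the macrophage identity list had a median log2 fold change of -0.015. Of its 30 members 12 were above 0 and 18 below, and C1qc and C1qa fell when adjusted over the list alone. The median argues against a loss of macrophages as large as the fall of Lyz2, while a smaller shift in cell composition stays open. A shift of reads to the paralog Lyz1 is argued against by the summed counts of Lyz1 and Lyz2, which had a log2 fold change of -1.04. The 95% interval of the Lyz2 fold change, -1.25 to -0.84 around -1.04, holds the value of -1 that the loss of 1 of 2 alleles would give. That value was set after the fold change was seen, so it is no independent test. A candidate explanation is a Cre gene inserted into Lyz2, a common design for myeloid deletion that the labels do not name. Regulation of Lyz2 by the loss of Dhps stays open and was not tested. With such an insertion in the knockout cells alone, the other changes could not be told apart from effects of Cre or of lower Lyz2.

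Of 13 measured granulocyte genes 12 had a log2 fold change above 0 and 5 passed, and the list was called higher with the preset correlation but not with an estimated correlation (adjusted p = 0.210) or by fry (0.070). The rise did not rest on 1 knockout library, since the lowest median log2 fold change with each left out was 0.74. A larger share of granulocyte-lineage RNA may account for it. The lists of megakaryocyte (median 0.64), mast cell (0.31) and monocyte markers (0.32) were called higher with the same limit (adjusted p = 0.210, 0.418 and 0.210 with an estimated correlation), and Pf4 (-0.29, from 1517 CPM) and Vwf (-0.12, from 81.4 CPM) had values below 0. Tubb1, Gp9, Mcpt8 and Prss34 are in the table through the knockout libraries alone, which favours a higher call for the megakaryocyte and mast cell lists. The bootstrap 95% intervals of these 2 medians included 0 (from -0.12 and -0.11). The granulocyte genes did not rise by 1 common fold (Cochran's Q of 64.5, where a common fold would give about 12). Among them Csf3r (0.19, from 37.9 CPM) and Mmp8 (-0.020, from 30.5 CPM) were near 0. How much of any of these marker genes the macrophages themselves express was not tested.

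The lists of ribosomal proteins and oxidative phosphorylation were called lower with the preset correlation but not with an estimated correlation (adjusted p = 0.907 and 0.306), and without knockout library 2 the ribosomal median was -0.0058. A GC trend as the whole cause is argued against, since 2 of the 2 lists were still called after it was removed (adjusted p = 0.012 and 0.0028). After a length trend was removed, 0 of the 2 lists were called, and 7 of all lists in place of 10: on mean log2 CPM, the ribosomal median went from -0.073 (bootstrap 95% interval -0.088 to -0.043) to -0.039 (-0.062 to -0.0018, adjusted p = 0.215) and the oxidative phosphorylation median from -0.070 (-0.11 to -0.045) to -0.043 (-0.072 to -0.0068, adjusted p = 0.120). Camera's shift, the mean moderated z of a list minus that of the other genes, went from -0.535 to -0.279 and from -0.616 to -0.356 while its SE stayed at 0.16 and 0.17, so the calls ended through smaller shifts and not through a wider spread. The medians kept 52.97% and 61.7% of their size after this trend, fitted on genes outside both lists, was removed. Both lists hold short genes (a median exon length of 725 and 756 bases, against 2958 over all genes). A length trend may thus account for part of each median. Whether the rest goes with genotype was not settled, since neither list was still called. The libraries' slopes on log2 exon length overlapped, from -0.012 to 0.0026 in control and from -0.00098 to 0.0092 in knockout libraries.

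Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many genes (11, with 0 as the highest of the others) and 1 called as many lists (10, with 9 as the highest of the others). 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the real split had 684 genes and the others between 246 and 1068. Those above the real split had 1068, 819 and 697. Genes within 5 Mb of Lyz2 or Dhps reached an unadjusted p under 0.05 in 4 of 104 cases against 678 of 10445 elsewhere (odds ratio 0.576, 95% interval 0.154 to 1.53, Fisher's exact test one-sided p = 0.911), so that an effect of flanking DNA was not detectable with this number of genes.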
